A study of Mus musculus with 8 samples.

How the data were processed

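The deposited data were 1 table of values for 28853 probe sets on 8 Affymetrix whole-transcript arrays. Per the labels' protocols, feeder cells were removed after trypsin treatment, total RNA was extracted with Trizol, and 100 ng were labelled for each array. The authors made the values with RMA in Partek, per the submitters' processing notes, and the version, the probe set definitions and the background options are not given in the sources used here. The deposited values were taken to be on a log2 scale because the largest, 13.8, lies above the natural log of the largest 16-bit scanner reading (11.1) and under its log2 (16.0). They were not centred by gene, and the smallest was 0.765. The median log2 value per array ran from 4.33 to 4.40. No array repeated another.

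The platform annotation listed 23410 of the probe sets, of which 21789 had 1 gene symbol and 1621 had several, and 5443 were not listed and are unnamed here. For each gene the probe set with the highest mean over all 8 arrays was used among probe sets with 1 symbol, which left 19938 genes, 999 of them with more than 1 probe set. Of the probe sets with 1 symbol, 21698 had a gene identifier present in the RefSeq gene table of assembly GRCm38.p6, which was used for names and chromosomes only. The array's genome build is not given in the sources used here, so no positions are given.

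Samples were grouped by the treatment in the labels, with 4 arrays each, and by day. All tests were moderated tests of limma 3.58.1 in R 4.3.3 (lmFit and eBayes), two-sided, with Benjamini-Hochberg adjustment over 19938 genes and a threshold of 0.05. The vitamin C effect over days was the treatment term beside day as a factor with 4 levels (3 residual degrees of freedom, 6.03 prior). The interaction and the slopes per treatment came from 1 model with treatment and a slope on day for each treatment (4 residual degrees of freedom, 6.43 prior). That model did not pair the 2 arrays of a day. For the vitamin C effect over days they were taken as a pair because day is a factor of the design. The deviations of the 2 arrays of a day from their treatment means correlated with 0.371, 0.18, 0.125 and 0.475 on days 3 to 6. Some neighbouring days correlated as much (0.238 for untreated day 4 with vitamin C day 3, 0.272 for untreated day 6 with vitamin C day 5), so these correlations also reflect the course in time and the pairing rests on the day in the labels. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 served for tables and plots.

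Before the data were examined, 24 gene lists with 607 entries were fixed, of which 549 matched a gene by symbol. They were tested against all other genes with camera at an inter-gene correlation of 0.01, adjusted over the lists of a comparison, with an estimated correlation as an alternative. The fry test, another alternative, asks whether the genes of a list move on balance in 1 direction, without setting them against other genes. The genes to name were fixed by rule at the same time: for the vitamin C effect the 12 largest rises and 12 largest falls past the threshold with 1 direction on all days, for the interaction and each slope the 6 steepest in each direction, with 5 genes that did not pass where fewer than 5 passed, up to 4 members of each list with the smallest p, and Pou5f1, Sox2, Klf4, Myc, Nanog, Esrrb, Zfp42, Dppa3, Cdh1, Thy1 and Col1a1. Predicted genes, clone names and olfactory receptors were counted and not named, except Gm6083, which is named further below after its value was seen. Where a list is described, other members past the threshold are named as well to complete its count.

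The alternatives were quantile normalization again, centring on array medians, leaving out the dimmest genes, testing each probe set, averaging the probe sets of a gene, eBayes with trend and robust options, other thresholds, other uses of day, and leaving out days or arrays in turn. The alternative for values not on a log scale did not apply. The vitamin C effect and the untreated slope both use the untreated arrays, but with 1 array on each of 4 evenly spaced days an estimated slope is independent of the estimated mean.

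The tests were checked on simulated arrays with the spread of the real genes and with 66 or 67 changed genes for each size of change. The noise was drawn independently for each gene and array, in 1 draw per comparison. These checks therefore do not cover variation that genes share within an array. For the vitamin C effect over days, 13.4% of changes of 0.5, 71.6% of changes of 1 and 97% of changes of 2 on the log2 scale were found among 19938 genes, with 0 false calls among 121. For the interaction, 0% of changes of 1 and 42.4% of changes of 2 over 3 days were found, with 1 false call among 29. For the slopes, changes of 2 over 3 days were found in 69.7% of cases without and 81.8% with vitamin C. With no change simulated, 0 genes were called in any of the 4 comparisons.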

Results

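Gene expression was measured in a mouse pre-iPSC clone, that is, in cells on the way from a somatic cell to an induced pluripotent stem cell that had not completed it. The cells, named MaF pre-iPSC9P2 in the labels, grew on feeder cells in mouse embryonic stem cell medium. Vitamin C (ascorbate) was added at 50 µg/ml from day 2 onwards, or left out, and cells were collected on days 3, 4, 5 and 6. There were 8 arrays, 4 untreated and 4 with vitamin C, 1 for each treatment and day. A difference on a single day therefore has no replicate. Errors given for single genes are limma's moderated standard errors, in which the spread of each gene is drawn towards that of all genes. The labels do not say that the days came from separate cultures, so p-values measure only the spread between these arrays, which may be technical, and the number of arrays limits the precision. In the test over days this spread also holds any change of the difference with day. A gene whose difference grew can therefore miss the threshold in that test.

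The arrays were alike as a whole, with correlations between pairs of arrays from 0.977 to 0.994 across 28853 probe sets. The first principal component held 43% of the variance and followed the day, from -25.9 in the untreated array of day 3 to 13.1 in that of day 6, and from -21.3 to 41.1 in the arrays with vitamin C. On each day the array with vitamin C also lay higher on this component, and that of day 5 (24.2) lay beyond the untreated array of day 6. The second component, with 16.8%, separated the treatments on every day, with untreated arrays between 6.43 and 19.5 and arrays with vitamin C between -24.2 and -2.35. Median log2 values of the arrays lay between 4.33 and 4.40.

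The first question was which genes differed between cells with and without vitamin C over all 4 days. Vitamin C went with much higher RNA levels of several genes of the pluripotent state. Dppa5a, an RNA-binding protein gene of pluripotent cells, was 10.8-fold higher (log2 difference 3.44 ± 0.18, moderated SE, adjusted p = 0.000275). Dppa2, a chromatin-associated gene of the same cells, was higher by 3.33 ± 0.31 (moderated SE, adjusted p = 0.00517). The SD of the 4 daily differences was 0.53 for Dppa5a and 1.01 for Dppa2. Nanog, a central transcription factor of pluripotency, was 3.46-fold higher (1.79 ± 0.14, adjusted p = 0.00164), by 1.51 on day 3 and by 2.11 on day 6. Among the fixed gene lists, 8 of 31 epithelial genes rose, and 7 of 28 mesenchymal genes fell, among them Acta2, Zeb1 and Vim, beside feeder or fibroblast markers with a median of -0.44. The shifts of these 3 lists in camera were lost with an estimated correlation (adjusted p = 0.308 with an estimated correlation for the epithelial, adjusted p = 0.0774 with an estimated correlation for the mesenchymal list and adjusted p = 0.359 with an estimated correlation for the markers). In all, 150 of 19938 genes passed the test, 107 higher and 43 lower with vitamin C. All 150 differed in the same direction on each of the 4 days, which their selection for a small spread over days largely fixes.

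The other large rises were outside the pluripotency list. Morc1, known for silencing transposons in male germ cells, rose by 3.09 ± 0.22 on the log2 scale, from a mean of 3.82 to 6.90. The lectin genes Clec2g and Clec2i rose by 2.64 and 2.28, Dmrtc1b by 2.43, the receptor gene Gpr179 by 2.37 and Serpina1c of the antitrypsin family by 2.13. Cers3, a ceramide synthase, rose by 1.70, the carbonic anhydrase Car2 by 1.67 and the metalloprotease subunit Mep1b by 1.63. Adjusted p-values of these 9 genes ran from 0.00128 to 0.0197, and each missed the threshold in 1 to 4 of 14 alternative settings (1 for Morc1 and Clec2g, 4 for Clec2i and Serpina1c). Of all 107 rises 98 passed without day 3, 3 without day 4, 9 without day 5 and 62 without day 6. Clec2g, Clec2i, Dmrtc1b and Serpina1c belong to families of close relatives, and whether their probes read 1 member alone is uncertain.

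The largest falls were smaller. Penk, which encodes the enkephalin precursor, differed by -1.32 ± 0.24 (log2, moderated SE, adjusted p = 0.0481), Ly6d by -1.25 and Ankrd1 by -1.18. The SD of the daily differences of Penk was 0.75. Lox, which cross-links collagen, differed by -1.16 ± 0.12 (adjusted p = 0.00721), and the smooth muscle actin genes Acta2 and Actg2 by -1.12 and -0.95. The protease inhibitor gene Timp3, the NAD synthesis gene Nmnat2, Efhd1, the RNase P subunit gene Pop1, the receptor kinase gene Axl and the adhesion gene Ncam1 also fell, with differences of -1.03, -1.01, -0.93, -0.90, -0.90 and -0.87. Each of these 12 falls missed the threshold in 2 to 6 of 14 alternative settings. In limma 0 of the 43 falls, mesenchymal genes included, passed without day 4 or without day 5, while all 43 kept an unadjusted p under 0.05, and 34 passed without day 3 and 17 without day 6. Those unadjusted p-values are no separate support, since the 43 were picked on the same days. With the mean of the feeder or fibroblast markers in place of day, a setting chosen after the data were seen, the differences were -0.25 for Lox (adjusted p = 0.682), -0.54 for Acta2 (adjusted p = 0.394) and -0.27 for Actg2 (adjusted p = 0.652). The other named falls shrank to different degrees. Over all 14 settings, this one included, the weakest values were -1.05 for Ly6d, -0.99 for Penk, -0.98 for Timp3, -0.85 for Nmnat2 and -0.76 for Efhd1. They were -0.66 for Ankrd1, -0.56 for Ncam1, -0.55 for Axl and -0.33 for Pop1, which kept a smaller share of its difference than Acta2.

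**Figure D1:**
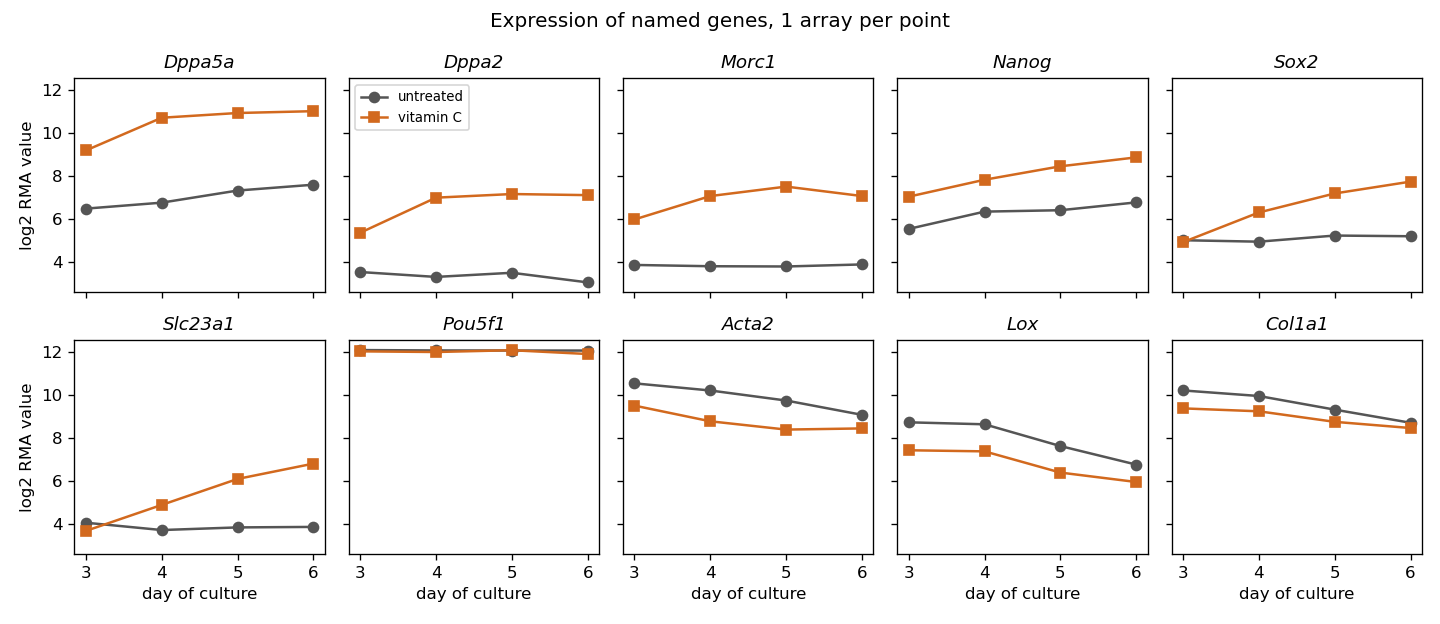
Log2 RMA value (vertical axis) of 10 genes against the day of culture (horizontal axis), with 1 array per point, untreated arrays as grey circles and arrays with vitamin C as orange squares. Dppa5a, Dppa2, Morc1 and Nanog were higher with vitamin C on each day, Sox2 and Slc23a1 diverged after day 3, Pou5f1 stayed between 11.9 and 12.1 in all arrays, and Acta2 and Lox were lower with vitamin C on each day.

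Of the 43 measured genes of the pluripotency network, 7 rose, 0 fell and 36 did not pass (24 rose when adjusted over the list alone). Besides Dppa5a, Dppa2 and Nanog these were Tfcp2l1 (1.01), Utf1 (1.10), Pecam1 (0.81) and Klf5 (0.60). The list as a whole was shifted up against other genes, with a median of 0.39 and 38 members above 0 (camera adjusted p = 2.57e-18, and adjusted p = 0.114 with an estimated correlation). Esrrb and Zfp42 did not pass, with differences of 1.21 (adjusted p = 0.0645) and 0.69 (adjusted p = 0.109), nor did Dppa3 with 0.21 (adjusted p = 0.745). The median of the feeder or fibroblast markers was -0.44 in the same comparison.

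Of the usual reprogramming factors, none of the 4 passed the test over days. Pou5f1 differed by -0.07 ± 0.10 at a mean level of 12.1, Klf4 by 0.01 ± 0.10, Myc by -0.11 ± 0.11 and Sox2 by 1.45 ± 0.34 (adjusted p = 0.104), and Sox2 alone passed when adjusted over the list alone. Whether the probes also read RNA of introduced copies of these genes is not given in the sources used here. The list was not called as shifted (camera adjusted p = 0.692), with a median of -0.03 and a mean of 0.32. The difference of Sox2 grew with day, as given further below, and this growth adds to its error in the test over days.

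Of 31 epithelial genes, 8 rose, 0 fell and 23 did not pass (25 rose when adjusted over the list alone). They were Ap1m2 (1.62), Grhl2 (1.52), Cldn4 (1.22), Ovol1 (1.19), Rab25 (1.13), Cldn6 (1.07), Cldn7 (0.87) and Pkp2 (0.69), which encode sorting, transcription and junction proteins of epithelia. The median of the list was 0.59 and 30 members lay above 0 (camera adjusted p = 5.34e-26, and adjusted p = 0.308 with an estimated correlation). Cdh1, the epithelial cadherin, did not pass, with 0.61 ± 0.11 (adjusted p = 0.0545). Feeder or fibroblast markers moved the other way, with a median of -0.44.

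Of 28 mesenchymal genes, 7 fell, 0 rose and 21 did not pass (15 fell when adjusted over the list alone). Acta2, Axl (-0.90), Zeb1 (-0.81), Tagln (-0.72), Tgfb3 (-0.70), Snai2 (-0.67) and Vim (-0.63) passed, of which Zeb1 and Snai2 encode repressors of epithelial genes. All 28 lay below 0, with a median of -0.42 (camera adjusted p = 5.55e-18, and adjusted p = 0.0774 with an estimated correlation). The feeder or fibroblast markers moved with them: 1 of 29, Col5a2 (-0.73), fell, 14 fell when adjusted over the list alone, and the median was -0.44 (camera adjusted p = 4.37e-15, and adjusted p = 0.359 with an estimated correlation). Their median difference was -0.51 on day 3, -0.70 on day 4, -0.39 on day 5 and -0.04 on day 6. Col1a1 and Thy1 did not pass, with -0.59 (adjusted p = 0.0752) and -0.18 (adjusted p = 0.621).

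Vitamin C is a cofactor of the dioxygenases that hydroxylate collagen, histones and DNA, so their genes were examined as lists. Of 17 genes of collagen hydroxylation and processing, Lox fell and 16 did not pass (8 fell when adjusted over the list alone, among them the prolyl 3-hydroxylase genes P3h1 with -0.59, P3h2 with -0.56 and P3h3 with -0.44), and the list was shifted down with a median of -0.29 (camera adjusted p = 1.76e-08, and adjusted p = 0.114 with an estimated correlation), beside the feeder or fibroblast markers with -0.44. Of 30 histone and DNA dioxygenase genes 0 passed, and 1, Tet1 with 0.47, passed when adjusted over the list alone (camera adjusted p = 0.404). Of 10 genes of the DNA methylation machinery 0 passed, and Dnmt3b (0.58), Dnmt3l (0.96), Dnmt3a (0.47) and Zfp57 (-0.41) passed when adjusted over the list alone (camera adjusted p = 0.722).

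Smaller shifts were called in 3 more lists. Of 15 trophoblast genes 3 rose, Rhox6 (1.28), Rhox9 (1.14) and Elf5 (0.94), and 12 did not pass (5 rose when adjusted over the list alone). The camera adjusted p of that list was 0.000157, and adjusted p = 0.408 with an estimated correlation. Of 31 germline genes Piwil2, a gene of the piRNA pathway, rose by 1.56 ± 0.16 and 30 did not pass (1 when adjusted over the list alone, camera adjusted p = 0.0228, and adjusted p = 0.359 with an estimated correlation). Of 19 genes of sterol synthesis 0 passed, over all genes or over the list alone, while the list had a median of 0.16 (camera adjusted p = 0.0016, and adjusted p = 0.359 with an estimated correlation).

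The other lists were not called by camera in this comparison. Camera adjusted p-values were 0.374 for the hypoxia response, 0.119 for p53 targets and senescence, 0.531 for imprinted genes, 0.13 for the cell cycle, 0.088 for the antioxidant response, 0.722 for the unfolded protein and amino acid response and 0.964 for the interferon response. They were 0.531 for endoderm, 0.979 for mesoderm, 0.18 for neurectoderm, 0.531 for blood cell markers, 0.832 for endothelial markers and 0.722 for the 5 measured genes of the two-cell-like list. No member of these lists passed over all genes in limma, against 150 of all 19938 genes, while 2531 of all genes had an unadjusted p under 0.05. The median and the direction of camera differed in sign for DNA methylation (-0.03, up), the reprogramming factors (-0.03, up), endothelial markers (-0.03, up) and the interferon response (0.05, down).

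**Figure D2:**
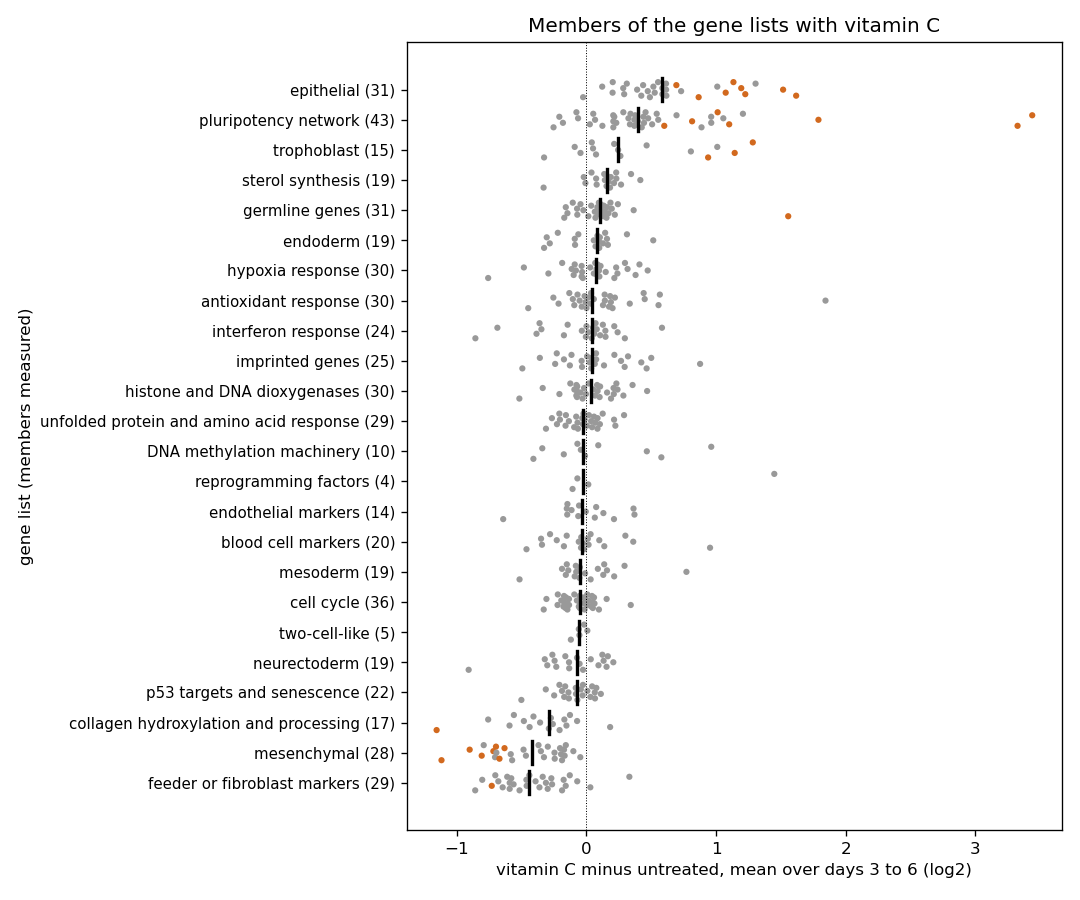
Vitamin C minus untreated difference (horizontal axis, log2, mean over days 3 to 6) of each measured member of the gene lists (vertical axis), orange where the adjusted p over all genes was under 0.05 and grey otherwise, with the list median as a black bar. The medians ran from -0.44 for feeder or fibroblast markers to 0.59 for epithelial genes.

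The number of genes called rested on the model and on the days. It was 17 with day left out of the model, 286 without day 3, 3 without day 4, 9 without day 5 and 13 with the mean of the feeder or fibroblast markers in place of day, a setting chosen after the data were seen. The balance of 107 higher and 43 lower moved as well, to 132 and 92 without the dimmest genes, 213 and 163 with trend and robust options, 170 and 121 with day as a number, 16 and 1 with day left out, 3 and 0 without day 4 and 9 and 0 without day 5. Dppa5a passed in all 14 alternative settings, with differences from 2.88 to 3.68, and Nanog passed without each single day but not with day left out (adjusted p = 0.152) or with the marker mean (1.24, adjusted p = 0.237).

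On single days, for which there is no test, the number of genes at least 2-fold higher with vitamin C was 74 on day 3, 128 on day 4, 192 on day 5 and 302 on day 6. The number at least 2-fold lower was 60, 90, 53 and 61. On all 4 days 11 genes were at least 2-fold higher, among them Dppa5a, Dppa2, Morc1, Nanog and Clec2g, and 0 were at least 2-fold lower.

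The second question was whether the vitamin C difference grew or shrank from day 3 to day 6. It grew for 13 genes, and the steepest was Slc23a1, which encodes a sodium-dependent vitamin C transporter. Its difference grew by 1.11 ± 0.10 per day (log2, SE, adjusted p = 0.0127), from -0.38 on day 3 to 2.96 on day 6. The placental gene Plac1 (1.08), the imprinted amino acid transporter gene Slc38a4 (1.01), the skin protease gene Asprv1 (0.99) and the adhesion receptor gene Adgrl2 (0.93) came next. The difference of Sox2, a reprogramming factor, grew by 0.85 ± 0.12 per day (adjusted p = 0.0391), from -0.09 to 2.55.

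Outside the 6 steepest, the remaining genes past the threshold were Ctsh (0.80), Tmsb4x (0.78), Lefty2 (0.76), Atp1b1 (0.74), Ankrd22 (0.70), Slc15a2 (0.67) and Cfap70 (0.62), of which Lefty2, a Nodal antagonist gene, was on a fixed list and the others are named after their values were seen. The limma test called 0 genes whose difference moved downwards, while 2244 genes had an unadjusted p under 0.05 in either direction. Among the steepest of the downward ones, none of which passed, Klrb1f had -0.65 per day, Hsd3b3 -0.62, Iqgap2 -0.60, Prrt3 -0.59 and Dio3 -0.59, with adjusted p-values from 0.0524 to 0.289.

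The interferon response list moved furthest. Its mean difference was -0.53 on day 3, -0.26 on day 4, 0.23 on day 5 and 0.43 on day 6, and the median change per day was 0.44 (camera adjusted p = 4.5e-12, and adjusted p = 0.215 with an estimated correlation). No member passed over all genes, and 15 of 24 passed when adjusted over the list alone, among them Ifit1 (0.83), Oasl2 (0.63) and Dhx58 (0.44). The epithelial list was shifted up with a median of 0.19 per day (0 passed, 3 over the list alone, camera adjusted p = 1.63e-08, and adjusted p = 0.364 with an estimated correlation). The feeder or fibroblast markers, lower with vitamin C early on, approached the untreated level by 0.17 per day in the median (0 passed, 1 over the list alone, camera adjusted p = 5.24e-06, and adjusted p = 0.43 with an estimated correlation).

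Upward shifts were also called for 7 lists in which at most 1 gene passed over all genes. They were imprinted genes (Slc38a4 passed, camera adjusted p = 2.87e-05, and adjusted p = 0.151 with an estimated correlation) and the pluripotency network (Lefty2 passed, camera adjusted p = 0.000107, and adjusted p = 0.103 with an estimated correlation). For trophoblast genes the camera adjusted p was 3.22e-05 and the adjusted p = 0.103 with an estimated correlation, for the hypoxia response 0.000107 and adjusted p = 0.5 with an estimated correlation, and for the antioxidant response 0.000632 and adjusted p = 0.151 with an estimated correlation. For collagen hydroxylation it was 0.0338 and adjusted p = 0.229 with an estimated correlation, and for endoderm 0.0338 and adjusted p = 0.519 with an estimated correlation. Adjusted over the list alone, 7 imprinted genes moved up and 1 down, 6 antioxidant genes moved up, and 3 genes each of the pluripotency and trophoblast lists moved up.

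The count of 13 was not firm. Without an untreated array it was 0 (day 3), 1 (day 4), 6 (day 5) and 0 (day 6), without an array with vitamin C it was 29 (day 3), 2 (day 5) and 2 (day 6), and it was 0 when days 5 and 6 were set against days 3 and 4.

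The third question was what changed with time in the untreated cells. From day 3 to day 6, 11 of 29 feeder or fibroblast markers, 7 of 28 mesenchymal genes and 7 of 24 interferon response genes fell, and 5 of 31 epithelial and 6 of 30 hypoxia response genes rose. As whole lists these passed in camera, but none did with an estimated correlation (adjusted p = 0.114 with an estimated correlation for the mesenchymal list and adjusted p = 0.224 with an estimated correlation for the other 4). The interferon-induced gene Ifit1 fell by 1.07 ± 0.10 per day (log2, SE, adjusted p = 0.0018), the iron-binding lipocalin gene Lcn2 by 0.93, the matrix protease genes Mmp13 and Mmp3 by 0.92 and 0.91, the chemokine gene Ccl2 by 0.90 and the cytokine gene Il6 by 0.89. Ace, the angiotensin-converting enzyme, rose by 0.86 per day, Igfbp2, Cbr2 and A2m by 0.84 each, and Car4 and Ndufa4l2 by 0.82. In all 349 genes passed, 156 rising and 193 falling. With the arrays centred on their medians, 130 rose and 255 fell.

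Of 29 feeder or fibroblast markers 11 fell, 0 rose and 18 did not pass (21 fell when adjusted over the list alone), with a median of -0.35 per day (camera adjusted p = 2.37e-18, and adjusted p = 0.224 with an estimated correlation), among them Pdgfrb (-0.59), Col1a2 (-0.53) and Col1a1 (-0.52). Of 28 mesenchymal genes 7 fell and 21 did not pass (15 fell over the list alone), such as Cdh11 (-0.61) and Prrx1 (-0.50), with camera adjusted p = 1.96e-12, and adjusted p = 0.114 with an estimated correlation. Of 30 hypoxia response genes 6 rose and 24 did not pass (15 rose over the list alone), such as Ndrg1 (0.79), Aldoc (0.78) and Egln3 (0.73), with camera adjusted p = 2.72e-13, and adjusted p = 0.224 with an estimated correlation. Of 31 epithelial genes 5 rose and 26 did not pass (18 rose over the list alone), such as Elf3 (0.59) and Cldn4 (0.62), with camera adjusted p = 1.96e-12, and adjusted p = 0.224 with an estimated correlation. Of 24 interferon response genes 7 fell and 17 did not pass (11 fell over the list alone), with camera adjusted p = 1.32e-08, and adjusted p = 0.224 with an estimated correlation.

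Shifts were called in 5 more lists without vitamin C. Of the pluripotency network 5 rose, such as Otx2 (0.71), Tdgf1 (0.58) and Nanog (0.38), with camera adjusted p = 0.00399, and adjusted p = 0.216 with an estimated correlation. The cell cycle list fell without a single member passing over all genes (camera adjusted p = 8.78e-08, and adjusted p = 0.361 with an estimated correlation). The antioxidant list was shifted down, with Slc7a11 (-0.55) and Nqo1 (-0.32) past the threshold (camera adjusted p = 0.00851, and adjusted p = 0.224 with an estimated correlation). The list of the unfolded protein and amino acid response was shifted down with 3 members falling and 1 rising (camera adjusted p = 0.0449, and adjusted p = 0.224 with an estimated correlation), and the mesoderm list up with Eomes (0.37) past the threshold (camera adjusted p = 0.00557, and adjusted p = 0.258 with an estimated correlation). The count of 349 became 74 without day 3, 179 without day 4, 222 without day 5 and 8 without day 6.

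In cells with vitamin C, 1722 genes changed with time, 1046 rising and 676 falling, and with the arrays centred on their medians 952 rose and 875 fell. The keratin genes Krt18 and Krt7 rose by 1.49 ± 0.13 and 1.22 ± 0.15 per day (log2, SE, adjusted p = 0.000313 and 0.00169), Asprv1 by 1.42, the epidermal gene Crct1 by 1.39, the angiomotin gene Amot by 1.35 and the kallikrein gene Klk7 by 1.14. Ces2g, a carboxylesterase with close relatives, fell by 0.79 per day, Iqgap2 by 0.76, the neurofilament gene Nefl and Akr1c18 by 0.70 each, Them5 by 0.69 and the desmoglein gene Dsg3 by 0.65. Of these 12 genes, Asprv1 alone passed the test of the difference in slopes between treatments (adjusted p = 0.0229).

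Of 31 epithelial genes 22 rose with vitamin C and 9 did not pass (27 rose over the list alone), with camera adjusted p = 6.54e-23, and adjusted p = 0.154 with an estimated correlation. Of 30 hypoxia response genes 19 rose and 11 did not pass (26 rose over the list alone), such as Bnip3 (0.95) and Aldoc (0.84), with camera adjusted p = 1.41e-20, and adjusted p = 0.205 with an estimated correlation. Of 43 pluripotency genes 18 rose, 2 fell and 23 did not pass (20 rose and 3 fell over the list alone), such as Lefty1 (1.04), Lefty2 (1.02) and Dppa4 (0.63). This list kept its shift with an estimated correlation (camera adjusted p = 9.83e-09, and adjusted p = 0.0463 with an estimated correlation), the 1 list of the 4 comparisons that did. Of 15 trophoblast genes 6 rose and 9 did not pass (8 rose over the list alone), with camera adjusted p = 1.01e-06, and adjusted p = 0.0604 with an estimated correlation. The reprogramming factor Sox2 rose by 0.94 ± 0.08 per day, and Pou5f1, Klf4 and Myc did not pass (camera adjusted p of their list 0.0475, and adjusted p = 0.289 with an estimated correlation).

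Markers of the feeder or fibroblast kind fell here too, 8 of 29 (12 over the list alone, camera adjusted p = 6.96e-05, and adjusted p = 0.473 with an estimated correlation), as did 6 of 28 mesenchymal genes while 1, Cnn2, rose (camera adjusted p = 1.99e-05, and adjusted p = 0.154 with an estimated correlation). Of 36 cell cycle genes 5 fell, such as Rrm2 (-0.54), and 31 did not pass (9 fell over the list alone, camera adjusted p = 3.79e-06, and adjusted p = 0.455 with an estimated correlation). Imprinted genes (6 rose, camera adjusted p = 0.00167, and adjusted p = 0.232 with an estimated correlation), endoderm genes (5 rose, camera adjusted p = 0.00268, and adjusted p = 0.455 with an estimated correlation) and dioxygenase genes (4 rose and 1 fell, camera adjusted p = 0.0475, and adjusted p = 0.455 with an estimated correlation) were shifted up. The count of 1722 became 775 without day 3, 1112 without day 5 and 270 without day 6.

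Of 349 genes that changed with time in untreated cells, 329 had a slope of the same sign with vitamin C, and of 1722 that changed with vitamin C, 1489 had a slope of the same sign without it. Of genes that passed in both, 118 rose in both, 75 fell in both and 0 went in opposite directions, where independent lists of these sizes would share 8.18 and 6.54. Across 19938 genes, which are not independent replicates, the slopes without and with vitamin C correlated with r = 0.493 and rho = 0.4, and the vitamin C effect over days correlated with the untreated slope with r = 0.252 and rho = 0.176. Of the 107 genes higher with vitamin C, 83 had an untreated slope above 0, against 51.6% of all genes, and of the 43 lower ones 34 had an untreated slope below 0.

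**Figure D3:**
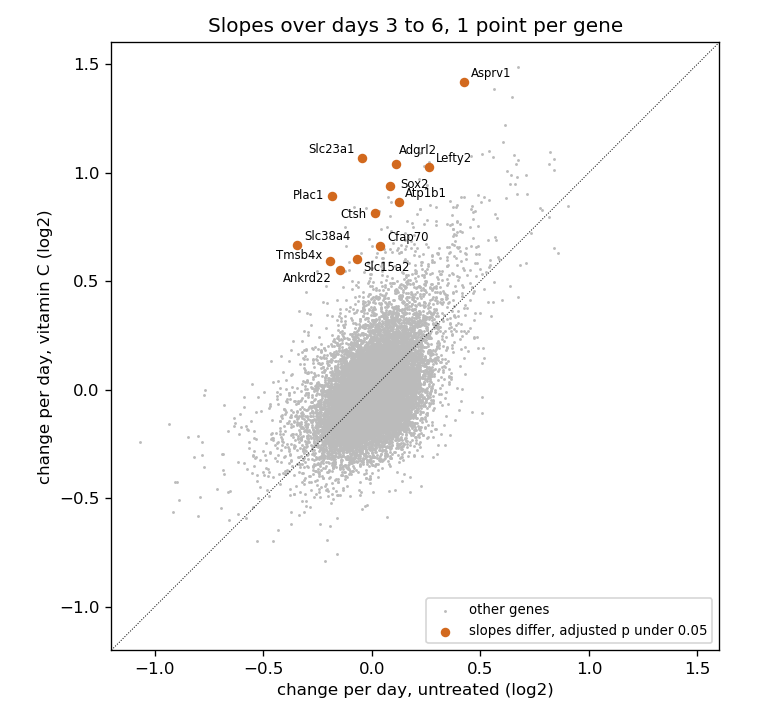
Change per day (log2) without vitamin C (horizontal axis) against that with vitamin C (vertical axis), 1 point per gene over 19938 genes, with the 13 genes whose slopes differed between the treatments in orange and the line of equal slopes dotted. All 13 lie above the line, and Slc23a1 had slopes of -0.05 without and 1.07 with vitamin C.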

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

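In this part all tests on feeder cells were chosen after the result was seen, several in turn for the same genes and each given below, and the other tests were chosen before.

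With vitamin C, 3 of 132 groups of 4 arrays (66 named genes in 2 treatments) held an array far from the other 3, where chance gives about 1 in 20. Dppa5a read 9.195 on day 3 against 10.73 to 11.03 on the later days, and Dppa2 read 5.345 on day 3 against 6.99 to 7.16. Dppa3 read 4.933 on day 4 against 4.18 to 4.25. The 4 arrays of a treatment are days of a time course, so a first day that stands apart is also what a rise by day 4 gives.

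The vitamin C difference changed with day in 13 genes by the interaction test. The changes per day were 1.112 for Slc23a1, 1.076 for Plac1, 1.008 for Slc38a4, 0.9923 for Asprv1, 0.9288 for Adgrl2, 0.8543 for Sox2, 0.8012 for Ctsh, 0.7842 for Tmsb4x, 0.7597 for Lefty2, 0.7436 for Atp1b1, 0.6977 for Ankrd22, 0.6703 for Slc15a2 and 0.6233 for Cfap70. Chance could not be excluded as the origin of this count: 2 of 35 splits of the 8 arrays into 2 groups of 4 called as many genes, and the highest other split called 66 against 13. That split set the untreated arrays of days 3, 5 and 6 and the treated array of day 3 against the rest. It is the real split with the untreated array of day 4 and the treated array of day 3 exchanged. Its calls can therefore carry much of the treatment difference, and why it called several times the real count was not tested. Among the 8 splits that part the 2 arrays of every day, the highest other count was 4.

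Of 7064 probe sets without 1 gene symbol, which the comparisons by gene left out, 11 differed with vitamin C when all probe sets were tested together, 10 higher and 1 lower. What they measure was not analysed here.

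For the 150 genes that differed with vitamin C over days, splits of the arrays do not decide whether chance gave the count. Of 32 splits in which the model could be fitted, 1, the real one, called as many genes, and the highest other split called 50. Most of the 32 leave both arrays of some days on the same side. Fewer pairs than in the real split then carry the difference, so a low count there says little. The 3 splits that could not be fitted put both arrays of a day on the same side for all days. The 8 splits that part the 2 arrays of every day are too few for a share under 0.05, and the highest of the other 7 called 0.

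For the 107 genes higher with vitamin C, fewer feeder cells in the treated samples would make the rise shrink as the deficit of the feeder or fibroblast markers closed, but the mean difference of the epithelial list, fixed beforehand, had a slope of 0.222 per day (SE 0.0929, 0.172 to 0.33 without each day in turn), while that of the markers was 0.165 (SE 0.096, 0.0831 without day 6 to 0.274 without day 3) and Pou5f1 differed by -0.07 ± 0.10. The mean difference of the pluripotency list, also fixed beforehand, had a slope of 0.1407 per day (SE 0.02516, 0.1001 to 0.1514 without each day). That list differed by 0.7867 on day 6, beside -0.08063 for the markers. A marker deficit that stayed level or closed would not let this rise grow. The values argue against feeder cells as the whole cause for this list, of which 7 of 43 genes are among the 107. For the 107 genes as a set, the course over the days leaves feeder cells undecided as the whole cause. The slope of the markers lies within 2 standard errors of 0. The slope of the 107 genes themselves, 0.1934 (SE 0.0722), decides nothing, since they were picked for steady differences. It was 0.0687 without day 3 and 0.324 without day 6. For 5 genes, the fewest that the test asked for and named here after their values were seen (Dppa5a, Dppa2, Morc1, Clec2g and the pseudogene Gm6083), a rise above the epithelial median plus 2 standard errors (0.77) in a one-sided test over all 19938 genes argues against the 1 common amount that fewer feeder cells would give, if epithelial genes stand for genes that feeder cells lack, while 2 earlier tests decide nothing: 74 of the 107 lay more than 2 standard errors above the epithelial median, but were picked for large differences, and with the marker mean in place of day their median went from 0.99 to 0.74, their median standard error from 0.141 to 0.229 and the calls to 8, where the marker mean correlates with treatment (r = -0.545) and replaces the day block, and which of these ended the calls was not tested. A gain of a chromosome is argued against by the chromosome median furthest from 0, -0.01952, and by no chromosome holding more than 11 of the 107 genes. An effect of vitamin C on the cells, the difference the design names, stays open as a hypothesis.

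For the 43 genes lower with vitamin C, the mean difference of the 42 that are not markers had a slope of -0.05384 per day (SE 0.0529), within 2 standard errors of 0, and of 0.048 without day 3 and -0.121 without day 6, which leaves fewer feeder cells open as the cause. Fewer feeder cells would also lower all genes that only feeder cells express by 1 common amount, and 0 of 19938 genes lay below the marker median minus 2 standard errors (-0.56) in a one-sided limma test with adjustment, 23 at an unadjusted p under 0.05. The earlier tests, of the change per day against the markers (-0.212 apart without day 6) and of the medians on day 6 (-0.74 and -0.04), decide nothing, because the 43 genes were picked for steady differences, which fixes a steady course. With the marker mean in place of day the median of the 43 genes went from -0.75 to -0.39, their median standard error from 0.117 to 0.161 and the calls to 3. Part of these falls may therefore come from fewer fibroblasts, and how many of them do was not settled. Penk, the largest named fall, did not follow the markers. Untreated, it rose by 0.46 per day (limma adjusted p = 0.0104), where the marker median changed by -0.35 per day. On day 6 it differed by -2.33, beside a marker median of -0.04. As 1 gene picked by its size it does not speak for the 43. The labels say that feeder cells were removed, yet abundant marker genes such as Col1a1 averaged 9.56 without and 8.96 with vitamin C, and 1 marker, Pdgfra, is also on the mesoderm list.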

How the results depend on the processing

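The covariate in place of day and the test of all probe sets were chosen after the data were seen, and the other settings before. The planned log2 of the value + 1 and + 16 was not run because the deposited values are already on a log scale. No gene that the fixed rule named and that passed changed its direction under the settings run for it. Quantile normalization again, centring on medians, averaging probe sets and testing each probe set left the counts of the vitamin C effect and of both slopes within 1.5 times. The cause of the larger changes was not tested, except that leaving out arrays or the day block changes the number of residual degrees of freedom.

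For the vitamin C effect over days, 150 genes (107 higher, 43 lower) became 376 with trend and robust options (213, 163), 291 with day as a number (170, 121), 564 with treatment by day as a number (331, 233), 399 with days 5 and 6 alone (325, 74), 384 at an adjusted p under 0.1 (222, 162) and 224 without the dimmest genes (132, 92). It became 17 with no replicate block, that is, without pairing by day, 13 with the marker mean in place of day and 79 over all probe sets. Leaving out a day gave 3 to 286 genes. Of the 150, 3 were kept without day 4, 9 without day 5, 79 without day 6 and 132 without day 3.

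For the interaction, 13 genes became 21 with quantile normalization again, 80 with trend and robust options, 42 at an adjusted p under 0.1 and 0 with days 5 and 6 against days 3 and 4, and leaving out 1 array gave 0 to 29. For the untreated slope, 349 became 580 without the dimmest genes, 782 with trend and robust options and 773 at an adjusted p under 0.1, and leaving out 1 array gave 8 to 222. For the slope with vitamin C, 1722 became 2917 at an adjusted p under 0.1, and leaving out 1 array gave 270 to 1680.

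Of the gene lists, 8 were called for the effect, and 0 with an estimated correlation and 3 by fry, which asks another question. For the interaction 10 became 0 with an estimated correlation and 0 by fry. For the untreated slope 10 became 0 with an estimated correlation and 12 by fry, which kept 9 of the 10. For the slope with vitamin C 11 became 1 with an estimated correlation and 7 by fry. Genes at least 1.5-fold rather than 2-fold apart numbered 1293 on day 3, 1599 on day 4, 1287 on day 5 and 1531 on day 6. Signal over background was not analysed here, and genes at low log2 values can have compressed differences.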

Other observations

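In this part the test on the course in time was chosen after the result was seen, in place of a first test whose outcome was against the hypothesis but which took the largest differences alone, and the test on the X chromosome was chosen before it, with a bound added after.

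Several genes with known roles in lipids or in the skin barrier were higher with vitamin C and are named here after their values were seen. They were the ceramide synthase Cers3 (1.70), the lipoxygenases Alox15 (1.40) and Alox12b (1.08), the transglutaminase Tgm1 (1.15), the plakin Ppl (1.09) and the ceramidase Acer1 (0.79), all past the threshold over all genes. No list for them was fixed, so no shift of a group is claimed. Gpx2, a glutathione peroxidase of epithelia, was the antioxidant gene with the largest difference, 1.84, and did not pass (adjusted p = 0.0674).

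Of 30 hypoxia response genes 6 rose with time without and 19 with vitamin C (adjusted p = 0.224 with an estimated correlation and adjusted p = 0.205 with an estimated correlation). These counts come from separate tests. In the interaction test 0 of the 30 genes passed, over all genes or over the list alone (camera adjusted p = 0.000107, and adjusted p = 0.5 with an estimated correlation). Their mean vitamin C difference was -0.16 on day 3, -0.14 on day 4, 0.29 on day 5 and 0.17 on day 6. The mean log2 value of the 24 interferon response genes, of which 7 fell without vitamin C (adjusted p = 0.224 with an estimated correlation for the list), was 5.24 on day 3 and 4.52 on day 6 without vitamin C, and 4.71 on day 3 and 4.94 on day 6 with vitamin C. What gave the higher level in untreated cells on day 3 was not tested.

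A hypothesis was that treated cells are ahead of untreated cells on the same course. The genes higher with vitamin C would then have an untreated rise of at least a 0.5 share of their difference, and a share under 0.25 would argue against it. The first test used the 12 largest rises alone, whose median untreated change over the 3 days was 0.10 against a difference of 2.32, which met the bound against the hypothesis. Those genes were picked by the difference that divides the ratio, so this excludes nothing. Over all 107 genes, which were picked by a test of that difference as well, the median untreated change was 0.41 against 0.99, a ratio of 0.4173 between both bounds. The hypothesis stays open.

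Another hypothesis was that genes on the X chromosome are frequent among those higher with vitamin C. In Fisher's exact test, two-sided, the odds ratio was 1.548 (95% interval 0.553 to 3.50, p = 0.295), with 6 of the 107 genes among 739 X-linked genes tested. The bound written beforehand took any p of 0.05 or more as evidence against an excess. That bound was wrong for so few genes, since the interval holds both no excess and one above 2-fold, so after the result was seen the outcome was set to undecided.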
